A study of Homo sapiens with 12 samples.

How the data were processed

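Libraries for 3' tag sequencing with a kit that marks the strand were made from total RNA of U937 and THP-1 cells kept for 24 h without or with 300 µg/mL EMD, with 15 PCR cycles, per the labels' protocols. No molecular identifiers are named there. There were 4 groups of 3 libraries. The samples were grouped by the cell line and treatment given in their labels, and no label mentions the TGF-beta receptor I kinase inhibitor that the design text names for some experiments. The deposited tables, 1 per cell line, hold whole-number read counts per gene that the authors did not normalise, per the file headers and the values. Per the submitters' processing notes, bcl2fastq, cutadapt 2.8, STAR 2.6.1a, DESeq2 1.22.2 and the genome build GRCh38 were used. Which role each had, how reads were assigned to genes and how reads with several matches were treated is not given in the sources used here. A 3' tag reads 1 site near the end of each transcript, so levels are not divided by transcript length. Genes with near-identical copies, such as HSPA1A, metallothioneins, ribosomal protein, HLA and LILR genes, APOC1 and the mitochondrial genes, are uncertain because the counting can split or drop shared reads.

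Both tables list the same 58780 genes in the same order, with the identifiers of GENCODE release 29, from which symbols and GRCh38 coordinates were taken. In 104 cases the deposited symbol differed from the annotation, 27 of them turned into dates, 32 reading PAR and 45 blank, and the symbol of the annotation was used. The column of the last library in each table carries 1 zero fewer than the sample title, which no other title resembles. All 12 columns were assigned to a sample. Total counts ran from 4950542 to 8317993, so that before TMM scaling a level of 1 CPM rests on 4.95 to 8.32 counts. Within the lines the TMM factors ran from 0.887 to 1.05 and shift this.

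Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a count minimum of 10. Libraries were scaled by TMM, and the quasi-likelihood F test was applied. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The EMD effect was fitted within each line on its 6 libraries. The difference of the effects is the interaction term of 1 model over all 12 libraries, given as the U937 effect minus the THP-1 effect. Untreated U937 was compared with untreated THP-1 on 6 libraries. Genes called in both lines were counted per direction and compared with independent lists by Fisher's exact test with both sides counted. Standard errors are the size of the log2 fold change divided by the square root of F. CPM were normalised by TMM within each comparison.

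Fixed gene lists, 26 in all with 618 members of which 1 had no identifier, were written before the data were examined, as were the comparisons, the alternatives and the rule for named genes. Pathway lists covered TGF-beta response, NF-kB inflammatory genes, interferon response, alternative activation, monocyte-macrophage identity, myeloid progenitor and granule, cholesterol synthesis, LXR targets and lipid storage. Others covered cell cycle, ER stress and amino acid response, NRF2 targets, metallothionein, lysosome, extracellular matrix and proteases, hypoxia and glycolysis. The rest covered antigen presentation, osteoclast, immediate early, complement and coagulation, mitochondrial RNA, ribosomal protein and enamel matrix genes, and markers of fibroblasts, epithelial, lymphoid and erythroid cells. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Fry was run as well, whose p asks whether the genes of a list move on balance one way without comparing them with other genes. Counts of called members are given adjusted over all genes and adjusted over the list alone.

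The rule for named genes took, for each EMD effect and for the difference, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change, with at least 5 CPM in the higher group and, for the EMD effects, no overlap between the groups. It then took up to 4 called members of each list by smallest p, and always SMAD7, SKIL, TGFBI, PMEPA1, TGFB1, IL1B, TNF, CXCL8, CCL2, IL10, MRC1 and 1 gene that is not reported here. For the untreated lines it took 6 per direction and the members of 4 lists. Part of these is summarised. Other genes are said to have been chosen after their values were seen.

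Alternatives were median-of-ratios size factors, library size as the only scaling, no filter beyond 1 count, a count minimum of 50, DESeq2 1.42.0, limma-voom, and a minimum absolute log2 fold change of 1. Further ones were each library left out in turn, the serial numbers of the titles as a block, and 1 fit over all 12 libraries. Leaving out the library of each line that stood apart was added for the difference, the lists and the overlap after the data were seen. Where a group held 0 counts, a fold is a lower bound with 3 counts over the group in place of 0. With 1 to 3 counts a ratio is given with a 95% interval. These bounds and ratios are scaled by total counts, without TMM. Figures were drawn with matplotlib 3.10.9.

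The fits were tested on simulated counts for the real genes with 200 of them changed. Of 100 genes changed by 1 and 100 changed by 2 on the log2 scale, 57 and 88 were recovered in the U937 comparison and 44 and 92 in the THP-1 comparison. For the difference 25 and 63 were recovered, and 50 and 81 between the untreated lines. In this order 3.97, 5.56, 10.2 and 4.38% of calls were false. Simulated genes were drawn independently of each other and no library stood apart, so these rates need not hold for the real data.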

Results

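RNA from 2 human monocytic cell lines was profiled by 3' tag sequencing after 24 h without or with 300 µg/mL enamel matrix derivative (EMD). EMD is an extract of developing tooth enamel, rich in amelogenins, that is applied in periodontal treatment. U937 was established from a pleural effusion of a histiocytic lymphoma, and THP-1 from the blood of a patient with acute monocytic leukemia. Both serve as models of monocytes and macrophages, and the design text of the series describes them as differentiated cells. Each line had 3 untreated and 3 EMD-treated libraries, 12 in all. Total counts ran from 7741280 to 8317993 in U937 and from 4950542 to 5655696 in THP-1. Before TMM scaling a level of 1 CPM stood for 4.95 counts in the shallowest library and 8.32 in the deepest. Between 13952 and 16063 genes had a count in U937 libraries, and between 14490 and 15103 in THP-1 libraries. Nothing in the sources used here says that the 3 libraries of a group came from separate cultures. If they did not, the p-values measure only the spread between these samples. CPM are given as means ± SD over n = 3 libraries per group. All gene calls are at a Benjamini-Hochberg adjusted p under 0.05 from edgeR's quasi-likelihood test.

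On the first principal component of its line, a single library in each line stood apart from the other 5. Untreated THP-1 library 1 lay at -57.7 while the other THP-1 libraries lay between -8.42 and 22.0. Untreated U937 library 3 lay at -58.4 while the others lay between -9.25 and 26.9. On the second component the U937 libraries numbered 3 lay at -38.5 with EMD and -19.1 untreated, and the others between 4.34 and 24.0. Untreated THP-1 library 1 carried heat shock transcripts far above the other 5 THP-1 libraries, a set of genes chosen after their values were seen. HSPA6, an inducible heat shock protein 70, was at 373 CPM in it and between 36.1 and 49.8 CPM in the others. The co-chaperone DNAJB1 was at 638 CPM against 76.2 to 96.8 CPM. For HSPA1A, which shares nearly all of its sequence with HSPA1B and is therefore uncertain, the values were 511 CPM against 62.9 to 95.3 CPM. Untreated U937 library 3 had the fewest genes with a count, 13952. No 2 libraries of a group agreed within the noise of independent counts, which PCR reads without named molecular identifiers can exceed by themselves. The chi-square of their counts per degree of freedom was at least 4.02. It reached 22.2 and 28.9 for the pairs with untreated THP-1 library 1, against 6.75 for the remaining untreated THP-1 pair.

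The first comparison asked how EMD changes the transcriptome of U937 cells. The transcript of osteopontin, SPP1, a secreted matrix phosphoprotein, rose from 5418 ± 379 CPM in untreated cells to 19632 ± 1354 CPM with EMD (log2 fold change 1.86, SE 0.091, adjusted p = 5.62e-11; GRCh38, ENSG00000118785.13, chromosome 4, 87975650 to 87983426). The costimulatory ligand CD86 rose from 23.2 ± 0.884 to 79.8 ± 3.16 CPM (log2 1.78, SE 0.14, adjusted p = 1.05e-07; ENSG00000114013.15, chromosome 3, 122055366 to 122121139). IL1RN, the interleukin-1 receptor antagonist, rose from 158 ± 42.6 to 456 ± 37 CPM (log2 1.52, SE 0.15, adjusted p = 9.88e-07; ENSG00000136689.18, chromosome 2, 113107214 to 113134016). OLR1, the receptor for oxidised low density lipoprotein, went from 0.252 ± 0.437 to 11 ± 2.70 CPM. The collagen-binding integrin subunit ITGA1 went from 0.703 ± 0.410 to 12.5 ± 2.10 CPM, and the scavenger receptor MSR1 from 4.33 ± 1.18 to 33.6 ± 1.21 CPM. The chemokine transcripts CCL8 and CCL1 fell, from 16.8 ± 5.37 to 0.758 ± 0.671 CPM and from 40.4 ± 14.9 to 3.30 ± 1.14 CPM (log2 -4.45 and -3.61).

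Among called genes with at least 5 CPM in the higher group, ITGA2, another collagen-binding integrin subunit, had the largest rise in U937. As its untreated libraries held 1 count in all, its change is given as a ratio of 172 (30.4 to 6816) with a 95% counting interval. The 8 largest rises by that limit also included OLR1, ITGA1, SLC11A1 (a metal transporter of phagosomes, log2 4.06), MMP3 (stromelysin-1, log2 3.12) and F5 (coagulation factor V, log2 3.03). All 6 untreated counts of OLR1 came from library 1, without which its fitted change was 9.48 in place of 5.40, a value that is no bound as the group then held 0 counts. Besides CCL8 and CCL1, the largest falls included RIN2, a guanine nucleotide exchange factor of RAB5 (log2 -3.05). LILRB2, an inhibitory immunoglobulin-like receptor whose reads near-identical family members can share, fell as well (log2 -2.61). In total 672 of 11580 tested genes changed in U937, 323 higher and 349 lower with EMD, of which 232 by at least 1 on the log2 scale. In 665 of the 672 all 3 values of one group lay above all 3 of the other, which held for 23.2% of all tested genes and by chance is reached by 10%. With library size as the only scaling the count was 754, 274 higher and 480 lower. The count fell to 347 without EMD library 1, to 362 without EMD library 2 and to 368 in 1 fit over all 12 libraries, and was 503 without EMD library 3.

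Genes of the extracellular matrix and its proteases rose as a group in U937, where 8 of 26 tested members were higher and 2 lower (10 higher and 4 lower adjusted over the list alone). The median log2 fold change was 0.31, and camera gave an adjusted p = 1.01e-07, or adjusted p = 0.0610 with an estimated correlation. Beyond SPP1 and MMP3, the protease inhibitors TIMP1 (log2 0.75) and SERPINE2 (log2 1.04) rose, while MMP9, gelatinase B, fell (log2 -1.34). The alternative activation list rose, and 4 of 12 tested members were higher and 2 lower (the same counts adjusted over the list alone). The median of this list was 0.17, and camera gave an adjusted p = 0.000588, or adjusted p = 0.146 with an estimated correlation. Its members MSR1 and the nuclear receptor PPARG rose by 2.95 and 1.02. In the complement and coagulation list 5 of 15 members were higher and 3 lower (6 higher and 5 lower adjusted over the list alone). Across the members the median was -0.094 while the mean was 0.28 and the test was upward, and camera gave an adjusted p = 0.00925, or adjusted p = 0.139 with an estimated correlation. There the anticoagulant receptors PROCR (log2 1.76) and THBD (log2 1.16) and the complement inhibitor CD55 (log2 1.07) rose. The anaphylatoxin receptor C3AR1 fell (log2 -1.48). For LXR targets and lipid storage, 3 of 17 members were higher and 0 lower (4 higher and 0 lower adjusted over the list alone). The list median was 0.012 and the mean 0.45, and camera gave an adjusted p = 0.00202, or adjusted p = 0.146 with an estimated correlation. FABP5, a fatty acid binding protein, rose by 1.31, and the lipid droplet coat protein PLIN2 rose from 741 ± 34.6 to 1528 ± 52.7 CPM (log2 1.04). PLIN2 was not called in 1 fit over all 12 libraries, which gave the highest adjusted p of its alternatives, 6.87e-38 to 0.263.

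Messenger RNAs encoded by the mitochondrial genome rose in U937, where 9 of 13 tested members were higher and 0 lower (10 higher and 0 lower adjusted over the list alone). Over the whole list the median was 0.50, and camera gave an adjusted p = 3.84e-11, or adjusted p = 0.0806 with an estimated correlation. MT-CO2, a subunit of cytochrome c oxidase, went from 7719 ± 207 to 11990.4 ± 89 CPM (log2 0.64). These genes have nuclear copies that can share reads. Their mean log2 levels relative to the line were -0.28, -0.25 and -0.081 in untreated libraries 1, 2 and 3, the third being the one that stood apart, and 0.17, 0.19 and 0.25 with EMD. Ribosomal protein genes also lay higher, although 2 of 34 tested members were higher and 0 lower (17 higher and 0 lower adjusted over the list alone). At the level of the list, the median was 0.26, and camera gave an adjusted p = 1.01e-07, or adjusted p = 0.355 with an estimated correlation. So did metallothioneins, of which 1 of 7 tested members were higher and 0 lower (4 higher and 0 lower adjusted over the list alone). The median log2 fold change was 0.36, and camera gave an adjusted p = 0.0149, or adjusted p = 0.139 with an estimated correlation. Members of both families are similar in sequence and therefore uncertain one by one.

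Several groups fell in U937. In the cholesterol synthesis list 0 of 22 members were higher and 3 lower (0 higher and 5 lower adjusted over the list alone). The median of this list was -0.19, and camera gave an adjusted p = 0.000107, or adjusted p = 0.0610 with an estimated correlation. SQLE, squalene epoxidase, fell from 849 ± 82.1 to 408 ± 39.2 CPM (log2 -1.06, SE 0.11, adjusted p = 1.89e-06; ENSG00000104549.11, chromosome 8, 124998497 to 125022283). HMGCS1, the cytosolic HMG-CoA synthase, was also called (log2 -0.43, adjusted p = 0.0326). It was not called without untreated library 1 (0.0931) or 2 (0.0605) or EMD library 1 (0.0576), 2 (0.0934) or 3 (0.158). Over all alternatives its adjusted p ran from 0.0113 to 0.263, the highest in 1 fit over all 12 libraries. The ER stress and amino acid response list fell, and 0 of 28 members were higher and 4 lower (0 higher and 11 lower adjusted over the list alone). Across the members the median was -0.19, and camera gave an adjusted p = 0.000166, or adjusted p = 0.0610 with an estimated correlation. The pseudokinase TRIB3 was at log2 -0.66. NRF2 targets fell too, and 0 of 19 were higher and 6 lower (2 higher and 9 lower adjusted over the list alone). The list median was -0.29, and camera gave an adjusted p = 0.000174, or adjusted p = 0.0610 with an estimated correlation. The peroxiredoxin PRDX1 was at log2 -0.73. Of the lysosome genes, which fell, 0 of 31 were higher and 5 lower (the same counts adjusted over the list alone). Over the whole list the median was -0.20, and camera gave an adjusted p = 0.000454, or adjusted p = 0.210 with an estimated correlation. Among them the protease CTSB, cathepsin B, fell from 3336 ± 364 to 1746 ± 149 CPM (log2 -0.93). The osteoclast list fell, and 0 of 13 members were higher and 4 lower (0 higher and 5 lower adjusted over the list alone). At the level of the list, the median was -0.41, and camera gave an adjusted p = 0.000315, or adjusted p = 0.0621 with an estimated correlation. OCSTAMP, a membrane protein needed for osteoclast fusion, fell from 128 ± 5.79 to 53.9 ± 6.21 CPM.

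Inflammatory genes went both ways in U937. In the NF-kB list 5 of 28 tested members were higher and 11 lower (5 higher and 13 lower adjusted over the list alone). The median log2 fold change was -0.30, and camera gave an adjusted p = 0.0443, or adjusted p = 0.588 with an estimated correlation. Without untreated library 3 the list did not pass (adjusted p = 0.775). TNF fell from 46.8 ± 4.92 to 21.8 ± 7.53 CPM (log2 -1.10, adjusted p = 0.00170). The T cell attracting chemokine CCL5 (log2 -1.25) and the adhesion molecule ICAM1 (log2 -1.13) fell as well. The chemokine CCL20 rose from 31.5 ± 2.33 to 118 ± 11.9 CPM (log2 1.91), and CXCL8, interleukin-8, rose by 0.49 (adjusted p = 0.00282). In 1 fit over all 12 libraries neither TNF nor CXCL8 was called. Over the alternatives their adjusted p ran from 8.41e-08 to 0.050 and from 8.66e-07 to 0.524. IL1B (0.33, adjusted p = 0.235) and CCL2 (-0.24, adjusted p = 0.154) were not called, though DESeq2 called CCL2 (0.0474 to 0.710 over the alternatives). Of the interferon response genes, 1 of 17 were higher and 2 lower (1 higher and 4 lower adjusted over the list alone). The median of this list was -0.16, and camera gave an adjusted p = 0.0214, or adjusted p = 0.139 with an estimated correlation. Markers of monocytes and macrophages split, and 7 of 30 were higher and 7 lower (8 higher and 9 lower adjusted over the list alone). Their median was -0.0032 and their mean -0.0055 with an upward test, and the camera adjusted p = 0.571. CD86, the endotoxin receptor TLR4 (log2 0.93) and lysozyme, LYZ (log2 0.95), rose. The integrin subunit ITGAM fell from 250.3 ± 24.7 to 133 ± 11.2 CPM (log2 -0.91).

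TGF-beta target genes were followed because the design text names an inhibitor of the TGF-beta receptor I kinase, although no sample label mentions it. In U937 4 of 28 tested members were higher and 4 lower (6 higher and 6 lower adjusted over the list alone), with a median of 0.14 and a camera adjusted p = 0.771. RUNX1, a transcription factor, rose (log2 0.61) and SMAD3, a signal transducer of the pathway, fell (log2 -1.21). SKIL, a feedback repressor, was called at log2 0.64 (adjusted p = 0.0353). It was not called without untreated library 1 (0.157) or 2 (0.0854) or EMD library 1 (0.252) or 2 (0.123), with library size only or in 1 fit over all 12 libraries. Its adjusted p over all alternatives ran from 0.00648 to 0.252. The feedback inhibitor SMAD7 (0.30, adjusted p = 0.460), PMEPA1 (1.24, 0.135) and TGFB1 (0.24, 0.414) were not called. TGFBI was too low to test in U937, IL10 had at most 15 counts in a library, and MRC1 had 0 counts in all 12 libraries.

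The remaining lists were not called in U937. Of the myeloid progenitor and granule list 1 of 14 were higher and 0 lower (the same counts adjusted over the list alone), with a median of 0.15 and a camera adjusted p = 0.324. Of the hypoxia and glycolysis list 0 of 22 were higher and 3 lower (the same counts adjusted over the list alone), with a median of 0.033, a mean of 0.027, a downward test and a camera adjusted p = 0.490. Among immediate early genes 5 of 28 were higher and 3 lower (6 higher and 3 lower adjusted over the list alone), with a median of -0.014, a mean of 0.11 and a camera adjusted p = 0.378. No gene was called by edgeR among 31 cell cycle and 12 antigen presentation genes, adjusted over the list alone either. In U937 2048 genes of all kinds had an unadjusted p under 0.05 and DESeq2 called 750. The cell cycle list had a median of 0.072 and a camera adjusted p = 0.589. The antigen presentation list had a median of -0.011, an upward test and a camera adjusted p = 0.735. Markers of other cell types were barely measured. The fibroblast protease FAP, the only member of its list tested, rose from 12.4 ± 2.48 to 43.1 ± 4.74 CPM (log2 1.79). A single epithelial and a single lymphoid marker were tested and not called, and no erythroid marker passed the filter. TUFT1, the 1 enamel gene tested, was not called (log2 2.21, adjusted p = 0.136). Its unadjusted p was under 0.05, like that of 2048 genes, and a list of 1 leaves nothing to adjust.

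**Figure D1:**
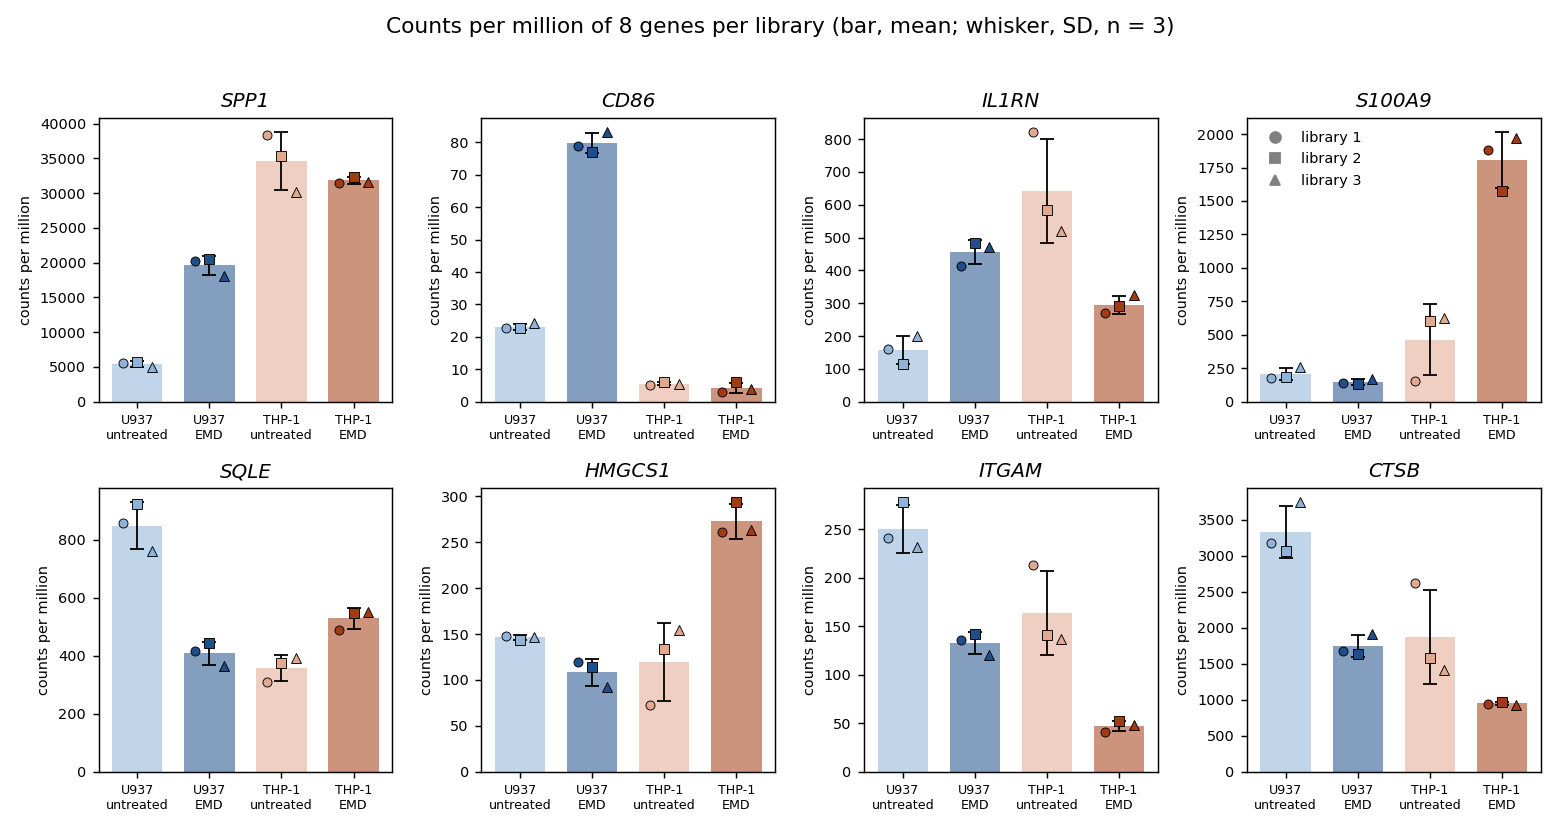
Normalised counts in CPM (vertical axes, linear from 0) of SPP1, CD86, IL1RN, S100A9, SQLE, HMGCS1, ITGAM and CTSB in the 4 groups of 3 libraries, with bars for the mean, whiskers for the SD and a marker per library. In U937 the bar of SPP1 stands at 5418 CPM untreated and 19632 CPM with EMD, and in THP-1 the bar of S100A9 at 462 and 1808 CPM.

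The second comparison asked the same question in THP-1. The integrin subunit ITGAM fell from 164 ± 43 to 47.3 ± 5.29 CPM (log2 -1.79, SE 0.19, adjusted p = 0.00736; ENSG00000169896.17, chromosome 16, 31259967 to 31332892). PIK3IP1, an inhibitor of phosphoinositide 3-kinase, rose from 8.31 ± 2.41 to 33.7 ± 2.43 CPM (log2 2.01, SE 0.23, adjusted p = 0.00978; ENSG00000100100.12, chromosome 22, 31281593 to 31292534). Fibronectin, FN1, rose from 132 ± 22.5 to 300.1 ± 37.6 CPM (log2 1.19). S100A8 and S100A9, the calcium-binding subunits of calprotectin, rose from 408 ± 265 to 1959 ± 151 CPM and from 462 ± 264 to 1808 ± 209.9 CPM (log2 2.26 and 1.97). IL1RN fell from 642 ± 159.7 to 296 ± 27.2 CPM, and the complement receptor C5AR1 from 114 ± 21.8 to 51.3 ± 1.07 CPM (log2 -1.12 and -1.15). Among the largest falls were the fructose transporter SLC2A5 (log2 -5.11), the ribonucleotide reductase subunit RRM2 (-3.81), the collagenase MMP1 (-3.58) and RGS2, a regulator of G protein signalling (-2.77). Without untreated library 1 the first 3 were -2.77, -2.31 and -2.29. The same 3 were not called by limma-voom, nor SLC2A5 with library size only, and over the alternatives their adjusted p ran from 9.62e-44 to 0.35, from 6.58e-34 to 0.228 and from 1.16e-53 to 0.209. In all, 215 of 10571 tested genes changed in THP-1, 61 higher and 154 lower, 113 of them by at least 1 on the log2 scale. In each of the 215 the groups did not overlap, which held for 22.6% of all tested genes, where chance gives 10%.

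The THP-1 count changed with the libraries. No gene was called by edgeR without EMD library 1 or 3, with smallest adjusted p of 0.0866 and 0.0943, and 1 was called without EMD library 2. In these 3 settings 1240, 1259 and 1244 genes had an unadjusted p under 0.05, and DESeq2 called 138, 162 and 158. The log2 changes of ITGAM then were -1.71, -1.81 and -1.87, those of PIK3IP1 2.06, 2.02 and 1.95 and those of S100A8 2.27, 2.20 and 2.31. The count was 657 without untreated library 1, 29 without untreated library 2 and 483 without untreated library 3. It was 378 with DESeq2, 132 with limma-voom, 744 with no filter on low counts and 478 in 1 fit over all 12 libraries. ITGAM, PIK3IP1, FN1, IL1RN and C5AR1 were called without any 1 untreated library. S100A8, S100A9, SLC2A5, RRM2, MMP1 and RGS2 were not called without untreated library 2, with adjusted p from 0.0515 for MMP1 to 0.0702 for S100A8.

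Genes of cholesterol synthesis rose together in THP-1, where 8 of 22 tested members were higher and 0 lower (17 higher and 1 lower adjusted over the list alone). Across the members the median was 0.70, and camera gave an adjusted p = 1.85e-17, or adjusted p = 0.211 with an estimated correlation. DHCR7, the last enzyme of the pathway, rose from 154 ± 30.7 to 339 ± 15.2 CPM (log2 1.14). HMGCS1 rose from 119.9 ± 42.4 to 273 ± 18.6 CPM (log2 1.18), and the decarboxylase MVD by 0.96. The mean log2 levels of the list relative to the line were -0.62, -0.19 and -0.17 in untreated libraries 1, 2 and 3, the first being the one that stood apart, and 0.33, 0.29 and 0.36 with EMD. Genes of hypoxia and glycolysis fell, and 0 of 24 were higher and 8 lower (0 higher and 21 lower adjusted over the list alone). The list median was -1.11, and camera gave an adjusted p = 1.62e-18, or adjusted p = 0.269 with an estimated correlation. The vasodilator peptide gene ADM fell from 116 ± 112 to 14.4 ± 4.09 CPM. The enolase ENO2 (log2 -2.23) and the glucose transporter SLC2A3 (log2 -1.57) fell too. This list had mean levels of 1.43, 0.32 and -0.13 in the untreated libraries and -0.67, -0.47 and -0.48 with EMD. Without untreated library 1 its median was -0.62, with 15 members lower. The changes of ADM, ENO2 and SLC2A3 then were -1.90, -1.35 and -0.94. SLC2A3 was not called by DESeq2, nor ADM and SLC2A3 with a count minimum of 50. Limma-voom called none of these 3 genes, and over the alternatives their adjusted p reached 0.231, 0.213 and 0.220 from lows of 7.17e-53, 3.19e-36 and 1.09e-27. Without untreated library 2, ADM (0.0702), ENO2 (0.0533), SLC2A3 (0.0641), HMGCS1 (0.0655) and MVD (0.0605) lost their calls. By edgeR the genes named here, like all others in THP-1, were not called without EMD library 1 or 3, where 1240 and 1259 genes had an unadjusted p under 0.05 and DESeq2 called 138 and 162.

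The ER stress and amino acid response list fell in THP-1, and 0 of 27 members were higher and 4 lower (0 higher and 8 lower adjusted over the list alone). Over the whole list the median was -0.35, and camera gave an adjusted p = 1.55e-05, or adjusted p = 0.127 with an estimated correlation. The stress-induced transcription factor DDIT3 was at log2 -0.85. Lysosome genes fell, and 0 of 30 were higher and 1 lower (0 higher and 9 lower adjusted over the list alone). At the level of the list, the median was -0.29, and camera gave an adjusted p = 4.32e-05, or adjusted p = 0.211 with an estimated correlation. The called gene was CTSB, which fell from 1874 ± 654 to 951 ± 23 CPM (log2 -0.98). Of the osteoclast list, which fell, 0 of 12 were higher and 2 lower (0 higher and 3 lower adjusted over the list alone). The median log2 fold change was -0.27, and camera gave an adjusted p = 0.0156, or adjusted p = 0.211 with an estimated correlation. Of the cell cycle list, which fell, 0 of 22 were higher and 1 lower (the same counts adjusted over the list alone). The median of this list was -0.31, and camera gave an adjusted p = 0.0156, or adjusted p = 0.269 with an estimated correlation. LXR targets and lipid storage fell, and 0 of 18 were higher and 1 lower (2 higher and 9 lower adjusted over the list alone). Across the members the median was -0.39, and camera gave an adjusted p = 0.0213, or adjusted p = 0.344 with an estimated correlation. Their mean levels were 0.59, 0.076 and -0.10 in untreated libraries 1, 2 and 3 and -0.20, -0.18 and -0.19 with EMD. Without untreated library 1 this list did not pass (adjusted p = 0.0638). The myeloid progenitor and granule list rose, although 0 of 12 were higher and 0 lower (3 higher and 0 lower adjusted over the list alone) by edgeR. The list median was 0.46, and camera gave an adjusted p = 0.00297, or adjusted p = 0.269 with an estimated correlation. In the NF-kB list 0 of 24 were higher and 4 lower (3 higher and 5 lower adjusted over the list alone), with a median of -0.13 and a camera adjusted p = 0.121. Among the lower ones CCL5 went from 1305 ± 78.1 to 759 ± 15 CPM. Without untreated library 1 the NF-kB (adjusted p = 0.00437), metallothionein (1.62e-07) and ribosomal protein lists (1.42e-06) passed the camera test as well, and with an estimated correlation they then had an adjusted p = 0.321, 0.275 and 0.321. The edgeR calls of DDIT3, CTSB and CCL5 were lost without untreated library 2 (adjusted p = 0.0572, 0.0594 and 0.0515), and without EMD library 1 or 3. Beside these counts, 1701 THP-1 genes of all kinds had an unadjusted p under 0.05 and DESeq2 called 378.

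No TGF-beta target passed the test in THP-1 by edgeR, 0 of 30 and 0 adjusted over the list alone, where 1701 genes of all kinds had an unadjusted p under 0.05 and DESeq2 called 378. The list had a median of 0.0085, a mean of -0.047, an upward test and a camera adjusted p = 0.881. SMAD7 had a log2 fold change of -0.20 (adjusted p = 0.809), SKIL one of 0.28 (0.468), PMEPA1 of 0.33 (0.458), TGFBI of 0.80 (0.362) and TGFB1 of -0.15 (0.849). The cytokine genes IL1B (0.15, 0.852), TNF (0.31, 0.760), CXCL8 (-0.75, 0.364) and CCL2 (-1.22, 0.236) were not called either. With no filter on low counts CXCL8 and CCL2 were called. CCL2 was called at -1.64 without untreated library 1 and stood at -0.67 without untreated library 2. CXCL8 was called at -1.17 without untreated library 3 and stood at -0.43 without untreated library 2. Over the alternatives the adjusted p of CXCL8 ran from 2.28e-05 to 0.684 and that of CCL2 from 0.000843 to 0.577. SMAD7, TGFB1, IL1B and TNF changed sign without untreated library 1 and were not called there. Further lists were not called, and their medians and camera adjusted p follow. Interferon response had -0.016 with an upward test and 0.935, alternative activation -0.052 (mean 0.10, upward) and 0.846. NRF2 targets had -0.015 and 0.881, and metallothioneins -0.80 and 0.283. Antigen presentation had 0.058 and 0.474, and immediate early genes -0.20 and 0.101. Complement and coagulation had -0.070 with an upward test and 0.935. Mitochondrial RNA had 0.0096 and 0.881, and ribosomal protein genes 0.059 and 0.319. Of the monocyte-macrophage markers 2 of 27 were higher and 3 lower (5 higher and 6 lower adjusted over the list alone), with a median of -0.19 and a camera adjusted p = 0.474. Of the extracellular matrix list 1 of 23 were higher and 2 lower (1 higher and 3 lower adjusted over the list alone), with a median of -0.11 and a camera adjusted p = 0.784. Among markers of other cell types 1 fibroblast, 2 lymphoid and 2 enamel genes were tested and none was called by edgeR. Adjusted over the list alone TUFT1 (log2 2.57) and both lymphoid genes passed. No epithelial or erythroid marker passed the filter.

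**Figure D2:**
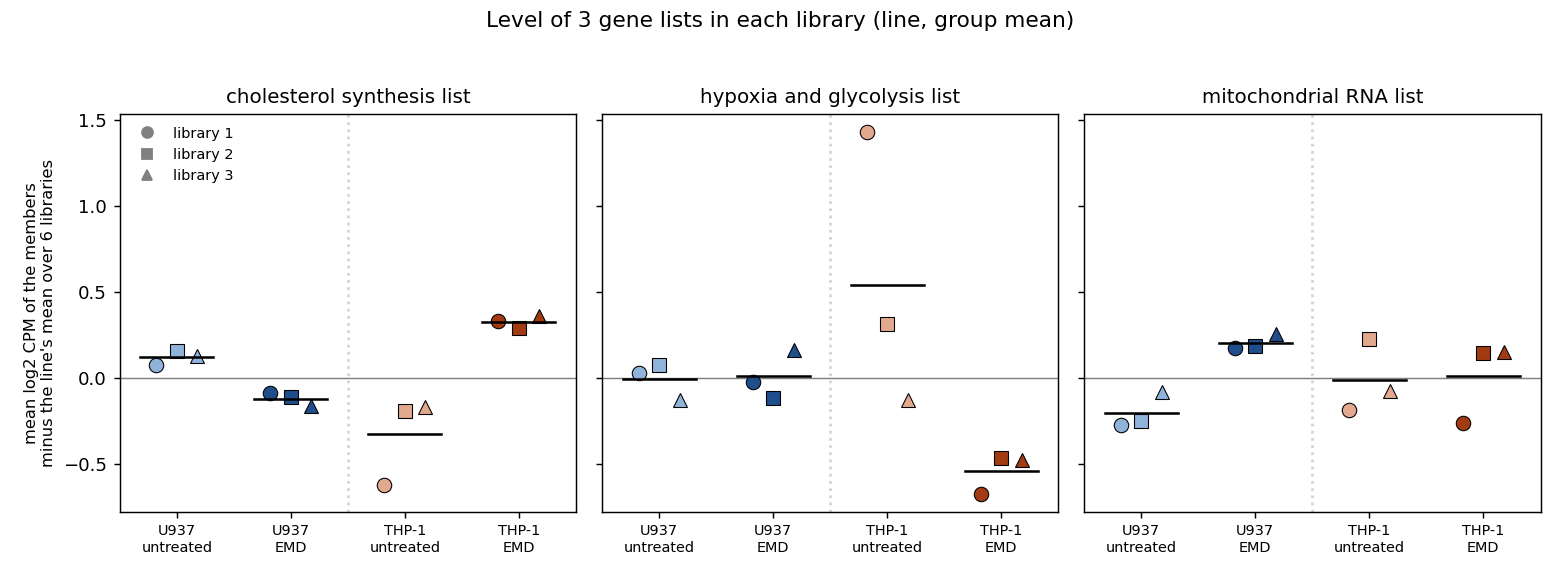
Mean log2 CPM of the tested members of the cholesterol synthesis, hypoxia and glycolysis, and mitochondrial RNA lists in each library, relative to the mean of the 6 libraries of its line (vertical axis, log2 units), for untreated and EMD-treated U937 and THP-1. Untreated THP-1 library 1 lies at 1.43 for hypoxia and glycolysis, and the 3 EMD-treated THP-1 libraries lie at -0.67, -0.47 and -0.48.

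The third comparison asked in which genes the response to EMD differed between the lines, as the U937 effect minus the THP-1 effect in 1 model of all 12 libraries. SPP1 rose in U937 and stood at a log2 change of -0.12 in THP-1 (adjusted p = 0.663), a difference of 1.97 (SE 0.16, adjusted p = 1.18e-06). IL1RN rose in U937 and fell in THP-1, a difference of 2.63 (SE 0.25, adjusted p = 1.12e-05). Differences in favour of U937 were also found for CD86 (2.15, adjusted p = 0.000736), TLR4 (2.19, 0.00160) and the apolipoprotein APOE (2.20, 0.000939). OLR1 differed by 5.17 (adjusted p = 9.96e-05), or by 8.82 without untreated U937 library 1, after which untreated U937 held 0 counts of it. SLA, an adaptor that dampens receptor signalling, differed the other way (-3.07, adjusted p = 3.23e-05), as did SQLE (-1.63, 3.23e-05) and the amino acid transporter SLC43A2 (-3.12, 0.00305). RIPOR2 (-4.46, 0.00485) and S100A9 (-2.46, 0.00494) did so too. In all 265 of 12342 tested genes differed, 160 with a higher effect in U937 and 105 with a lower one. By the tests within the lines, 74 of these rose and 47 fell in U937 alone, which means without a call in the other line. In THP-1 alone 22 rose and 45 fell. Another 12 changed in opposite directions, while 4 rose and 1 fell in both lines. Tested in both lines but called in neither were 21 with a higher and 25 with a lower effect in U937.

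The count of 265 genes depended on the libraries. It was 159, 133 and 153 without untreated U937 library 1, 2 or 3, and 128, 113 and 152 without EMD-treated U937 library 1, 2 or 3. Without EMD-treated THP-1 library 1, 2 or 3 it was 113, 110 and 122, and without untreated THP-1 library 3 it was 462. Without the libraries of both lines that stood apart, a setting added after the data were seen, it was 360, with 224 genes shared. DESeq2 called 412 genes and the fit with no filter on low counts 520. Of the 54 genes named for this comparison by size or list, 28 kept their call without each library in turn. OLR1, SLA, SLC43A2 and RIPOR2 were the 4 of the 16 largest differences among them. With library size as the only scaling the median over all genes moved to -0.11. None of the genes followed whatever the test said that are reported here was called by edgeR, while 1641 genes of all kinds had an unadjusted p under 0.05. TNF had a difference of -1.42 (adjusted p = 0.125; 0.00120 to 0.274 over the alternatives). CXCL8 had a difference of 1.2 (adjusted p = 0.175; 8.25e-09 to 0.388). CCL2 had a difference of 0.98 (adjusted p = 0.299; 0.000309 to 0.671). All 3 were called with no filter on low counts. Leaving out untreated THP-1 library 1 gave CCL2 a called difference of 1.4, and leaving out library 2 gave CCL2 one of 0.46, not called, and TNF a called one of -1.77. Leaving out library 3 gave CXCL8 a called one of 1.65. The others had differences of 0.89 for PMEPA1, 0.49 for SMAD7, 0.35 for SKIL, 0.37 for TGFB1, 0.17 for IL1B and 1.07 for TGFBI. Those of TGFB1 and IL1B changed sign with 1 library left out and were not called there. IL10 and MRC1 were too low to test. F5, MSR1, CCL8, LILRB2 and ITGA2 had 0 counts in all THP-1 libraries, so that no response of theirs could be compared.

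Cholesterol synthesis was the 1 list whose difference also passed with an estimated correlation. Of its 22 members 10 had a lower effect in U937 and 0 a higher one (0 higher and 17 lower adjusted over the list alone). Over the whole list the median was -0.95, and camera gave an adjusted p = 5.67e-25, or adjusted p = 0.0186 with an estimated correlation. The differences of DHCR7, HMGCS1 and MVD were -1.24, -1.62 and -1.48. In the hypoxia and glycolysis list 6 of 24 were higher and 0 lower (15 higher and 0 lower adjusted over the list alone). At the level of the list, the median was 0.97 (0.99 with members near 0 counts set at their bound), and camera gave an adjusted p = 5.28e-12, or adjusted p = 0.266 with an estimated correlation. Without untreated THP-1 library 1 the median was 0.56. The untreated levels of this list in THP-1 were 1.43, 0.32 and -0.13. Of LXR targets and lipid storage 3 of 20 were higher and 0 lower (8 higher and 1 lower adjusted over the list alone). The median difference was 0.59 (0.40 with members near 0 counts set at their bound), and camera gave an adjusted p = 4.83e-05, or adjusted p = 0.118 with an estimated correlation. The apolipoprotein gene APOC1, which has a close pseudogene, differed by 3.69. PLIN2 differed by 3.22, or by 1.81 without untreated THP-1 library 1. In the extracellular matrix list 7 of 28 were higher and 1 lower (9 higher and 2 lower adjusted over the list alone). The median of this list was 0.37, and camera gave an adjusted p = 1.81e-05, or adjusted p = 0.0955 with an estimated correlation. The protease MMP19 differed by 3.07 and FN1 by 2.78. FN1 was not called by limma-voom, and its adjusted p over the alternatives ran from 2.01e-07 to 0.220. Of the mitochondrial RNAs 1 of 13 were higher and 0 lower (6 higher and 0 lower adjusted over the list alone). Across the members the median was 0.44, and camera gave an adjusted p = 0.000114, or adjusted p = 0.303 with an estimated correlation. In the complement and coagulation list 3 of 15 were higher and 1 lower (5 higher and 1 lower adjusted over the list alone), CD55 among the higher ones (1.0). The list median was 0.68, and camera gave an adjusted p = 0.0204, or adjusted p = 0.230 with an estimated correlation.

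The difference passed also for the cell cycle list, where 1 of 32 genes were higher and 0 lower (the same counts adjusted over the list alone). Over the whole list the median was 0.38, and camera gave an adjusted p = 0.0190, or adjusted p = 0.266 with an estimated correlation. Of immediate early genes 3 of 28 were higher and 1 lower (5 higher and 2 lower adjusted over the list alone). At the level of the list, the median was 0.22, and camera gave an adjusted p = 0.0190, or adjusted p = 0.266 with an estimated correlation. The phosphatase DUSP1 (1.96) and PHLDA1 (1.61) had higher effects in U937. Of metallothioneins 1 of 7 were higher and 0 lower (3 higher and 0 lower adjusted over the list alone). The median difference was 0.68 (1.20 without untreated THP-1 library 1), and camera gave an adjusted p = 0.0169, or adjusted p = 0.30 with an estimated correlation. NRF2 targets had a lower effect in U937, and 0 of 20 were higher and 2 lower (1 higher and 5 lower adjusted over the list alone). The median of this list was -0.019 and the mean -0.25, and camera gave an adjusted p = 0.0315, or adjusted p = 0.266 with an estimated correlation. The call was lost without untreated THP-1 library 1 (adjusted p = 0.0979) and with library size only (adjusted p = 0.0529). Ribosomal protein genes had a higher effect, although 0 of 34 were higher and 0 lower (the same counts adjusted over the list alone) by edgeR. Across the members the median was 0.18, and camera gave an adjusted p = 0.0169, or adjusted p = 0.605 with an estimated correlation. This call was lost under the same settings (adjusted p = 0.235 and 0.104). The interferon list passed without untreated U937 library 3 (adjusted p = 0.0385, or adjusted p = 0.235 with an estimated correlation), and had an adjusted p = 0.0511 and a median of -0.40 with all libraries. Lists that were not called included TGF-beta response (median 0.27, 0.35 at the bound, camera adjusted p = 0.514), NF-kB (0.15, 0.534) and alternative activation (0.64, 0.191). The same held for monocyte-macrophage identity (-0.096 with an upward test, 0.534), myeloid progenitor (-0.17, -0.19 at the bound, 0.267) and ER stress genes (0.096, 0.232). It held also for lysosome (0.17, 0.204), antigen presentation (-0.10, -0.15 at the bound, 0.688) and osteoclast genes (0.0081 with a downward test, -0.035 at the bound, 0.817). Within these, the immunoglobulin receptor FCGR2A (0.92), the chemokine CCL20 (1.18) and PPARG (1.31) had higher effects in U937 and the superoxide dismutase SOD2 (-1.42) a lower one. None of the 6 tested markers of other cell types and enamel genes was called by edgeR, which called 265 genes in all against 412 by DESeq2 and 1641 at an unadjusted p under 0.05. Adjusted over the list alone 1 fibroblast marker had a higher effect in U937 and 1 of 2 lymphoid markers a lower one. The fibroblast marker was the only one tested of its list, which leaves its p unadjusted.

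The fourth comparison counted the genes called in both lines, among 9914 tested in both. ALOX5AP, the activating protein of 5-lipoxygenase, FN1, S100A8, SLC11A1 and PROCR were among 12 genes higher with EMD in both lines, where 1.58 would be shared by independent lists (two-sided Fisher's exact test, p = 3.68e-08). A further 34 were lower in both against 4.49 for independent lists (exact p = 5.38e-21), among them CTSB, ITGAM, CCL5, ICAM1, C3AR1 and SLC2A3. With library size only ICAM1 and C3AR1 lost their THP-1 calls, as did MT1X and RIPOR2, named next. Limma-voom did not call ICAM1, C3AR1 or MT1X in THP-1, nor did a count minimum of 50 leave C3AR1 and RIPOR2 called. Without untreated THP-1 library 2 the THP-1 change of C3AR1 was -1.42 and not called, against -2.38 with all libraries. Other genes went in opposite directions. DHRS3, DPYSL3, EDN1, IL1RN, LMO4, MT1X and RGS1 were higher in U937 and lower in THP-1, 7 genes against 4.02 for independent lists (exact p = 0.125). HMGCS1, RIPOR2, S100A9, SLA and TUBA1A were lower in U937 and higher in THP-1, 5 against 1.76 (exact p = 0.031). Several of these names fall outside the naming rule and were chosen after their values were seen, and all 12 passed the test of the difference. The exact tests take the genes as independent, so their p-values can be too small. Both counts of genes called in opposite directions also lay above those of independent lists, but only the 5 lower in U937 had an exact p under 0.05. Across the 9914 genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.14 and a Spearman correlation of 0.15. Of the 740 among them called in either line, 63.8% had the same sign in both. The 46 shared genes with the same direction became 119 without untreated THP-1 library 1, 6 without untreated THP-1 library 2 and 69 without untreated THP-1 library 3. They became 0 by edgeR without any 1 of the EMD-treated THP-1 libraries, where 1240 to 1259 THP-1 genes had an unadjusted p under 0.05 and DESeq2 called 138 to 162. DESeq2 gave 71 shared genes with all libraries, beside 21 in opposite directions. A minimum log2 change of 1 left 7, beside 6 in opposite directions. Without untreated THP-1 library 1, 2 or 3, 31, 3 and 36 genes were called in opposite directions, against 12 with all libraries.

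**Figure D3:**
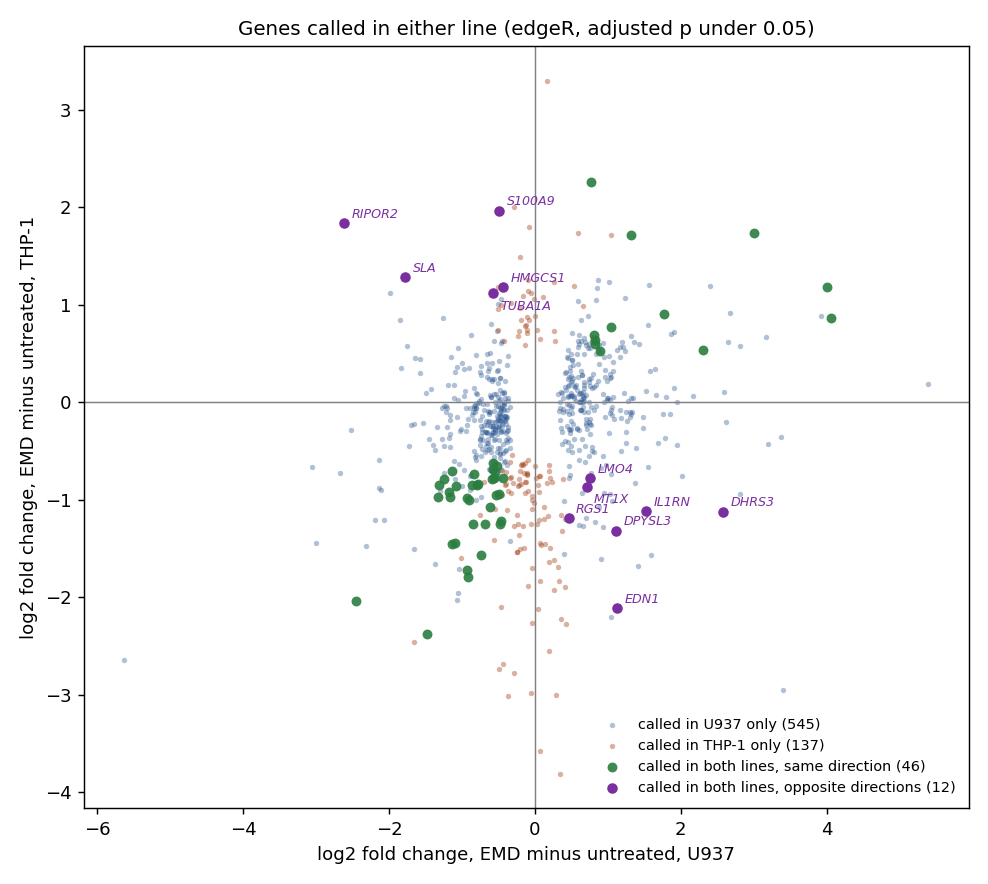
Log2 fold change with EMD in THP-1 (vertical axis) against that in U937 (horizontal axis). The 740 genes drawn were tested in both lines and called in at least 1. Colours show calls in U937 alone (545), in THP-1 alone (137), in both with the same direction (46) or in both with opposite directions (12, named). Called genes that were tested in 1 line only are not drawn. A call in 1 line alone is not a test of the difference between the lines.

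The last comparison set the untreated lines against each other. Each line had its own deposited table and its own series of library names, so that cell line and preparation cannot be told apart. Scaled by total counts, FABP4, the adipocyte and macrophage fatty acid binding protein, was at least 508-fold higher in untreated U937. LTBP1, a latent TGF-beta binding protein, was at least 158-fold higher, as untreated THP-1 held 0 counts of each. Lipoprotein lipase, LPL, was at least 2625-fold higher in THP-1 and the syndecan SDC2 at least 1196-fold. The transcription factor OLIG2 was at least 1057-fold higher there and the neutrophil granule enzyme MPO at least 116-fold, as untreated U937 held 0 counts of these 4. The bounds put 3 counts over the group in place of 0, and like the ratio given next they are scaled by total counts, without TMM. The median of all genes was 0.016 with TMM and 0.46 with library size only. Folds in favour of U937 are therefore smaller with TMM, and those in favour of THP-1 larger. The adhesion molecule CADM1 had a ratio of 1606 (288 to 63439) with its 95% counting interval, in favour of U937, where untreated THP-1 held 1 count. Such intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The matricellular protein gene NOV was higher in U937 (1182 ± 49.6 against 1.37 ± 1.67 CPM), as were the scavenger receptor MARCO (log2 5.91), the immunoglobulin receptor FCGR2A (1.53) and the class II gene HLA-DRB1 (4.71). CSF1R, the receptor of macrophage colony stimulating factor (-2.36), LILRB4 (-4.14), the class I gene HLA-B (-1.32) and HOXA9 (-2.68) were higher in THP-1. HLA and LILR genes share reads with close relatives and are uncertain.

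Of 11337 tested genes 5609 differed between the untreated lines, 2747 higher and 2862 lower in U937, 3731 of them by at least 1 on the log2 scale. In 5517 the groups did not overlap, which held for 59.4% of all tested genes and by chance for 10%. With library size only the split was 4443 higher and 1813 lower, as the median of all genes then moved to 0.46, and with DESeq2 that median was -0.10. All 34 ribosomal protein genes were lower in U937. The list median was -2.05, and camera gave an adjusted p = 1.63e-28, or adjusted p = 0.419 with an estimated correlation. All protein-coding genes with ribosomal protein symbols, a wider set than this list, took 7.67 to 9.79% of counts in U937 libraries and 22.1 to 25.3% in THP-1 libraries. Of the hypoxia and glycolysis genes 21 of 24 were lower in U937. Over the whole list the median was -2.46, and camera gave an adjusted p = 4.85e-06, or adjusted p = 0.474 with an estimated correlation. Untreated THP-1 library 1, at 1.43, lay above its fellows at 0.32 and -0.13. LXR targets (10 of 18 lower, 4 higher; median -1.58, camera adjusted p = 0.00170) and immediate early genes (13 of 28 lower, 4 higher; -0.60, 0.0184) were lower as well. Mitochondrial RNA (11 of 13 higher; median 1.16, camera adjusted p = 4.85e-06) and interferon response genes (10 of 17 higher, 1 lower; 1.80, 0.000426) were higher in U937. So were NRF2 targets (13 of 18 higher, 3 lower; 1.09, 0.000426) and cell cycle genes (17 of 30 higher, 4 lower; 1.18, 0.00280). For these 6 lists the adjusted p = 0.419 with an estimated correlation, except the interferon list at 0.365. Adjusted over the list alone the counts in these 8 lists were the same but for 1 more call each in the LXR, interferon and cell cycle lists.

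No other list was called between the untreated lines, and their medians and camera adjusted p follow. TGF-beta response had -0.47 and 0.0730, NF-kB 1.10 and 0.0911, and alternative activation 1.26 (mean -0.030, upward) and 0.444. Monocyte-macrophage identity had 0.097 and 0.444, myeloid progenitor and granule -1.18 and 0.183, and cholesterol synthesis -0.51 and 0.248. The ER stress list had -0.33 and 0.235, metallothionein -1.15 and 0.261, and lysosome 0.44 and 0.0546. Extracellular matrix had -0.23 and 0.109, and antigen presentation -0.87 and 0.0590. Osteoclast had -0.64 and 0.444, and complement and coagulation 0.14 and 0.444. Without untreated THP-1 library 1, the one that stood apart, camera called the NF-kB (adjusted p = 0.0356), metallothionein (0.0118), lysosome (0.00540) and antigen presentation lists (0.0356). With an estimated correlation these 4 lists then had an adjusted p = 0.520, 0.420, 0.420 and 0.420. The lysosome list was also called with library size only (adjusted p = 0.00871, or adjusted p = 0.390 with an estimated correlation). Of the TGF-beta targets 14 were lower and 2 higher in U937 of 30, and of the monocyte-macrophage markers 10 were higher and 10 lower of 30. Adjusted over the list alone the counts were the same. Of the markers of other cell types, FAP and the lymphoid gene NKG7 were higher in U937 (log2 2.53 and 2.57). The lymphoid gene GNLY (0.107 ± 0.186 against 7.58 ± 4.14 CPM) and the enamel gene FAM83H (0 counts in untreated U937 against 5.58 ± 1.54 CPM) were higher in THP-1. A single epithelial marker was tested and was not called, with an unadjusted p under 0.05 that a list of 1 leaves as it is.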

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

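The tests of the mitochondrial rRNA, of the direction of the hypoxia list and of other splits of the samples were chosen after the results were seen. The results here were taken up because the EMD effect differed between the lines by a test of the difference itself, which called 265 genes by edgeR and 11 lists by camera. The median difference was -0.95 for cholesterol synthesis, 0.59 for LXR targets and lipid storage, 0.38 for cell cycle, -0.019 for NRF2 targets, 0.68 for metallothionein and 0.37 for extracellular matrix and proteases. It was 0.97 for hypoxia and glycolysis, 0.22 for immediate early, 0.68 for complement and coagulation, 0.44 for mitochondrial RNA and 0.18 for ribosomal protein. The cholesterol synthesis list kept its call with an adjusted p = 0.0186, and the other 10 lists had adjusted p from 0.0955 to 0.605 with an estimated correlation. NRF2 targets and ribosomal protein genes lost their calls with library size only and without untreated THP-1 library 1.

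Log2 differences toward a higher effect in U937 that were called without each library were ALOX5AP 1.76, APOC1 3.69, APOE 2.20, CCL20 1.18, CD55 1.0, CD86 2.15 and DHRS3 3.68. Further ones of this kind were DPYSL3 2.42, DUSP1 1.96, EDN1 3.23, ENO2 2.58, FCGR2A 0.92, FN1 2.78 and IL1RN 2.63. Others were ITGA6 1.75, LMO4 1.52, MMP1 3.63, MMP19 3.07, MT1X 1.57, OLR1 5.17 and PHLDA1 1.61. The last of them were PLIN2 3.22, PPARG 1.31, RGS1 1.64, SERPINE2 1.13, SLC11A1 3.18, SPP1 1.97 and TLR4 2.19. Toward a lower effect in U937 they were DHCR7 -1.24, HMGCS1 -1.62, LILRA2 -0.95, MVD -1.48, PIK3IP1 -2.30, RIN2 -2.40, RIPOR2 -4.46, S100A9 -2.46, SLA -3.07, SLC43A2 -3.12, SOD2 -1.42, SQLE -1.63 and TUBA1A -1.71. With 1 library left out, differences moved over 1.5 times for MMP1 at 2.37 without untreated THP-1 library 1, OLR1 at 8.82 without untreated U937 library 1, PLIN2 at 1.81 without untreated THP-1 library 1, CADM1 at -6.32 without untreated THP-1 library 2, CCL1 at -8.65 without untreated THP-1 library 2, ITGA1 at 2.98 without untreated THP-1 library 3 and RRM2 at 2.66 without untreated THP-1 library 1. Without both libraries that stood apart ENO2 was at 1.57, also a move of that size, and still called.

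The genes named next were not called without the libraries given. C5AR1, with a log2 difference of 0.89, lost its call without untreated U937 library 1 or 2, EMD-treated U937 library 2 or 3 or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.0627). For CADM1 the difference was -3.93, and it was not called without any 1 of the untreated U937 libraries, any 1 of the EMD-treated U937 libraries, untreated THP-1 library 1 or 3 or EMD-treated THP-1 library 2 or 3 (adjusted p up to 0.377). The difference of CCL1, -5.41, was not past the threshold without EMD-treated U937 library 2 or EMD-treated THP-1 library 3 (adjusted p up to 0.390). ITGA1, with a log2 difference of 4.93, lost its call without any 1 of the untreated U937 libraries, any 1 of the EMD-treated U937 libraries, untreated THP-1 library 3 or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.556). For ITGA5 the difference was 0.82, and it was not called without untreated U937 library 1 or 2, any 1 of the EMD-treated U937 libraries or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.134). The difference of ITGAM, 0.87, was not past the threshold without any 1 of the untreated U937 libraries, any 1 of the EMD-treated U937 libraries or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.143).

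MMP9, with a log2 difference of -1.10, lost its call without EMD-treated U937 library 1 or 2, untreated THP-1 library 2 or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.0832). For PROCR the difference was 0.85, and it was not called without any 1 of the untreated U937 libraries, any 1 of the EMD-treated U937 libraries, untreated THP-1 library 2 or 3 or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.125). The difference of RGS2, 2.48, was not past the threshold without any 1 of the untreated U937 libraries, any 1 of the EMD-treated U937 libraries, untreated THP-1 library 2 or any 1 of the EMD-treated THP-1 libraries (adjusted p up to 0.108). RRM2, with a log2 difference of 4.14, lost its call without untreated U937 library 2, EMD-treated U937 library 2 or EMD-treated THP-1 library 1 or 3 (adjusted p up to 0.0627). For RUNX1 the difference was 1.08, and it was not called without EMD-treated U937 library 2 or EMD-treated THP-1 library 1 or 2 (adjusted p up to 0.0684). Untreated THP-1 held 1 count of CADM1 and 2 of CCL1, so that these fitted differences depend on the prior count and are no bounds. Limma-voom did not call CADM1, CCL1, ENO2, FN1, ITGA1, MMP1, PROCR or RRM2. PROCR also lost its call with library size only and with no filter on low counts, and ITGA1 and PROCR lost theirs with the replicate block.

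Of 100 drawn splits of the 12 libraries within their lines, only the real one gave as many genes with a difference. It called 265, against at most 89 in the others. Splits that mix treated and untreated libraries of a line also add the EMD effect to the spread. A low count in them can reflect an EMD effect common to both lines, so chance is not excluded for the difference. For U937 (672, highest other 0), THP-1 (215, highest other 0) and the untreated lines (5609, highest other 0), 1 of 10 splits, the real one, gave as many genes by edgeR. With 10 splits no share under 0.05 can be had. The other splits had 153 to 542, 210 to 514 and 30 to 165 genes at an unadjusted p under 0.05.

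The first pattern weighed is the fall of hypoxia and glycolysis genes in EMD-treated THP-1, a list with an adjusted p = 0.269 with an estimated correlation. Scaling between libraries is argued against as its cause, since the median was -1.01 with library size only. Untreated THP-1 library 1 alone does not account for the direction, as 15 members were called lower and 0 higher without it, and both other untreated libraries, 2 of 2, lay above every treated library. The median then was -0.62, between the bounds set in advance, so its part in the size of the fall cannot be told apart from an effect of EMD. An effect of EMD may explain part of the fall, and the state of the cultures at harvest, which was not tested, stays open as well.

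The next pattern is the opposite change of cholesterol synthesis genes, higher in THP-1 and lower in U937 with EMD. With an estimated correlation the difference kept its call (adjusted p = 0.0186), but the changes within THP-1 (adjusted p = 0.211) and within U937 (adjusted p = 0.0610, with 3 of 22 members called) did not. The median difference was -0.78 without untreated THP-1 library 1, -0.94 without untreated U937 library 3 and -1.04 with library size only, each past the bound set in advance against these explanations. A response to EMD that differs by cell line is a hypothesis that may explain it, but line and library series cannot be told apart in this design.

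The last pattern is the rise of mitochondrial mRNA in EMD-treated U937, a list with an adjusted p = 0.0806 with an estimated correlation. More mitochondrial RNA of every kind in the libraries is argued against, as the larger change of the mitochondrial rRNAs was 0.10 (MT-RNR2). Untreated U937 library 3 is argued against, as it lay nearest to the EMD-treated libraries, at -0.081 against -0.28 and -0.25 in untreated libraries 1 and 2. The median was 0.59 without it, but given that level leaving it out was no separate test. Nuclear copies that share reads and a difference in how polyadenylated transcripts were primed were not tested. A higher level of these mRNAs with EMD may be biological, but these explanations stay open.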

How the results depend on the processing

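Leaving out the libraries that stood apart was chosen after the data were seen. The number of genes called in U937, 672, was 232 with a minimum log2 change of 1, 368 in 1 fit over all 12 libraries and 347 to 612 with 1 library left out. In THP-1, 215 genes became 744 with no filter on low counts, 378 with DESeq2, 132 with limma-voom and 113 with a minimum log2 change of 1. They became 478 in 1 fit over all 12 libraries and 0 to 657 with 1 library left out. At the count of 0 by edgeR, 1240 and 1259 genes had an unadjusted p under 0.05 and DESeq2 called 138 and 162. For the difference between the lines, 265 became 520 with no filter, 412 with DESeq2 and 110 to 462 with 1 library left out, and 360 without both libraries that stood apart. Between the untreated lines a minimum log2 change of 1 left 3731 of 5609. The 46 genes shared by the lines with the same direction were 71 with DESeq2, 7 with a minimum log2 change of 1, 0 to 119 with 1 library left out and 109 without both libraries that stood apart. Beside the 71 and the 7, 21 and 6 genes were called in opposite directions. For all these the cause was not tested, except that a minimum change keeps fewer genes by construction.

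All other settings left the counts within 1.5 times of the main ones, and no result changed direction past the test. Of the single genes and lists recomputed under the alternatives set from the start, 3188 results kept their side of the threshold, 609 lost and 36 gained it. Under the added ones 170 kept, 11 lost and 9 gained it. Of 84 list results camera called 41 with its preset correlation. With an estimated correlation 40 of the 41 calls were lost, 1 was kept and none of the other 43 was gained. Fry kept 25 of the calls, ended 16 and added 10. Using the serial numbers of the titles as a replicate block gave 724 genes in U937, 237 in THP-1 and 227 for the difference. It changed 1 of 63 list results, as the interferon list then passed camera for the difference (adjusted p = 0.0346). Without the block, camera gave that list an adjusted p = 0.264 with an estimated correlation. Deviations of same-numbered libraries had correlations of -0.023, 0.013 and 0.081 in U937 and 0.0090, -0.040 and 0.039 in THP-1. Only pair 3 of each line correlated best with its own number, so the numbers were not taken to pair the libraries. In U937 the libraries numbered 3 had 13952 and 14712 genes with a count, against 15513 to 16063 in the others. They also lay lowest on the second component, so an effect of the serial number in U937 stays open. Setting members near 0 counts at their bound moved no list median by more than 0.19 over 84 list results. Depth limits what can be seen: before TMM scaling 1 CPM stood for 4.95 to 8.32 counts.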

Other observations

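The gene families here, and the counts of their members, were chosen after the values were seen, so that these tests were not planned. Integrin subunits, which carry cells on matrix and on other cells, changed unevenly in U937. Of 17 tested, 6 were higher with EMD and 4 lower by edgeR, or 5 and 4 with library size only. Besides the collagen-binding ITGA1 and ITGA2, the laminin-binding ITGA6 (log2 1.91), ITGAE (1.05), ITGAV (0.84) and ITGB5 (0.72) rose. Others fell, which were ITGA4 (-1.0), ITGAL (-0.44), ITGAM (-0.91) and ITGB2 (-1.08). In THP-1 0 of 15 were higher and 3 lower, ITGA5 (-0.75), ITGAM (-1.79) and ITGB2 (-0.86), among 1701 genes at an unadjusted p under 0.05 and 378 called by DESeq2. ITGA1, with 7 untreated and 4 treated counts in THP-1, and ITGA2, with 0 counts there, were not tested in that line. By edgeR no THP-1 call held without EMD library 1 or 3, where 1240 and 1259 genes had an unadjusted p under 0.05 and DESeq2 called 138 and 162.

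Among genes of leukotriene and prostanoid synthesis and their receptors, 4 of 14 tested in U937 were higher with EMD and 1 lower by edgeR. In THP-1 3 of 15 were higher and 1 lower. ALOX5AP, which presents arachidonic acid to 5-lipoxygenase, rose by 2.30 in U937 and 0.53 in THP-1. The leukotriene A4 hydrolase LTA4H rose by 0.82 and 0.69, and the microsomal glutathione transferase MGST1 by 0.90 and 0.53. PTGS2, the inducible cyclooxygenase, rose in U937 (0.81) and the leukotriene receptor CYSLTR1 fell there (-2.18), and PTGS1 fell in THP-1 (-0.70). ALOX5, the 5-lipoxygenase itself, did not pass the filter in U937 and was not called in THP-1 (log2 -0.41, adjusted p = 0.839). Of the difference tests ALOX5AP alone was called among 15 members by edgeR. These THP-1 calls by edgeR were also among those lost without EMD library 1 or 3.

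Immunoglobulin-like receptors of the LILR family, whose members share reads and are uncertain, were lower with EMD in U937 for LILRA2 (-1.20), LILRB1 (-1.73) and LILRB2 (-2.61) of 7 tested, or 4 with library size only. None of 5 was called in THP-1 by edgeR, where 1701 genes of all kinds had an unadjusted p under 0.05 and DESeq2 called 378.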
